A study of Mus musculus with 10 samples.

How the data were processed

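The series holds 10 RNA sequencing libraries from mouse leukaemic progenitor cells of a model named DIN. Fetal liver cells had been given 3 MSCV vectors, which carry DNMT3A R882H (under doxycycline control), IDH2 R140Q and NRAS G12D. Frozen leukaemic cells were transplanted into recipient mice, and the mice received doxycycline, which turns the DNMT3A R882H vector off, or no doxycycline. Cells positive for cKit and negative for Cd11b were sorted from bone marrow and spleen after 5 or 14 days. The labels put 4 libraries in the day 14 off group and 2 libraries in each of the day 14 on, day 5 off and day 5 on groups. They do not say which libraries came from marrow and which from spleen, nor whether each library is a separate mouse, so each p-value measures the spread between these libraries.

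Per the labels' protocols, RNA was extracted with Trizol and a Direct-zol kit, and libraries of polyA RNA were made with a QuantSeq 3′ mRNA kit and sequenced as single-end reads on a NextSeq500. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.0.4, featureCounts, Subread 2.0.0, edgeR 3.34.0, limma 3.48.3 and the mouse build mm10. Their settings, the strand setting and the annotation release are not given in the sources used here. The authors deposited raw read counts per Ensembl gene, with no normalisation, in 1 table of 52636 genes. Of the gene IDs, 52403 matched GENCODE release M21, from which symbols, biotypes and mm10 positions were taken, and 233 did not match. The per-library values were whole numbers, and 29010 genes had a count in at least 1 library.

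Total counts per library ran from 9292644 to 14340624, and 7 of the 10 totals lay above the highest depth that the labels' protocols state (10 x106 reads), and a count of 0 allows up to 0.209 CPM in the deepest library and 0.323 CPM in the shallowest (3 counts of the total). Such limits and the exact Clopper-Pearson 95% intervals of shares cover counting error only. Of overlapping gene pairs with a mean count of at least 20, 71 of 1105 on the same strand and 14 of 2040 on opposite strands had counts within 2% of each other in all 10 libraries. Reads in such overlaps were therefore counted for both genes, and counts of these pairs cannot be told apart by strand.

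Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 15916 genes, and libraries were scaled by TMM. Each comparison used edgeR's robust quasi-likelihood fit and its test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p of 0.05. One fit with a mean for each of the 4 groups covered all 10 libraries, so that the groups share 1 estimate of the spread. The comparison over both days used a model with day and doxycycline. Log2 fold changes are given with their standard errors, and CPM values are TMM-scaled group means with standard deviations. Off over on is the direction of every treatment change.

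Gene lists for pathways, cell types and library quality, 43 in all, were tested with limma's camera on edgeR's log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 40 lists with at least 5 tested genes. Camera with an estimated correlation and limma's fry were run beside it. No list was called with an estimated correlation in any comparison. The design, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names the genes of the 3 vectors, Kit and Itgam (the genes of the sort markers), the 9 heme synthesis genes and Fdx1 in every treatment comparison. It adds the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3, no overlap between groups and no predicted gene model. From each list that camera called, or that had at least 3 called genes, it takes up to 4 genes of smallest p. Of these the first 2 by p are carried through the alternatives, a number set after the values were seen and applied by rank alone. For the other comparisons it names the 3 genes of smallest p in each direction. Of the genes so named 4 are not described, 1 of them a heme synthesis gene, and no other gene takes their place, while the tests of genes and lists include them.

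Alternatives covered RLE scaling, no low-count filter, a filter at 5 CPM in at least 2 libraries, DESeq2's Wald test, limma voom, a replicate-number block, a 2-fold minimum, a fit of only the compared groups, and leaving out each of the 10 libraries in turn. An arm left with 1 library was assumed to vary like the other groups. Added after the data were seen were fits without 3 ribosomal RNA locus genes, fits of protein-coding genes without a partner that shares counts, counts thinned to the smallest library, and list tests on the difference between days. The edgeR comparisons and camera with the preset correlation were first checked on simulated counts with 200 changed genes among 15544 tested. For the difference between days and the comparisons over time only unchanged genes were checked, and edgeR called 0. In the day 14 comparison edgeR called 36% of 2-fold and 86% of 4-fold changes and 11 unchanged genes. The day 5 comparison called 25% and 71%, with 3 unchanged genes, and the comparison over both days called 62% and 91%, with 8 unchanged genes. Camera called 2 of 2 changed lists and 0 of 20 random lists in each of the 3 comparisons. The simulated genes were drawn independently of each other, so this check could not show how camera's preset correlation behaves on lists of correlated genes. All libraries and all count columns were used.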

Results

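Gene expression was measured in sorted cKit-positive, Cd11b-negative leukaemic cells from mice with the DNMT3A R882H vector turned off by doxycycline (off) or left on. There were 4 day 14 off libraries and 2 libraries each for day 14 on, day 5 off and day 5 on. Total counts were 11960995, 13220124, 14340624 and 10968353 at day 14 off, 9753834 and 10752147 at day 14 on, 9864398 and 11973117 at day 5 off, and 9292644 and 13327629 at day 5 on. Across genes, library correlations were 0.977 to 0.983 among day 14 off libraries and 0.897 to 0.913 between day 14 off and day 14 on libraries. The 3 genes at ribosomal RNA loci (CT010467.1, Gm42418 and AY036118) took from 7.78% of the counts in day 14 off replicate 3 (95% Clopper-Pearson interval 7.76% to 7.79%) to 16.5% in day 14 off replicate 4 (16.5% to 16.5%). Their separate shares were nearly equal, at 2.61%, 2.60% and 2.57% in replicate 3 and 5.56%, 5.51% and 5.41% in replicate 4. The same reads may therefore be counted more than once in these sums, while the intervals treat every count as a separate read.

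The series title asks about heme synthesis and copper-dependent cell death in acute myeloid leukaemia. The day 14 comparison asks which genes changed with doxycycline, which turns off the mutant methyltransferase. No library received doxycycline without the regulated vector. A direct effect of doxycycline on any gene therefore cannot be told apart from that of the vector. At day 14, most genes of heme synthesis were higher off than on. Cpox, coproporphyrinogen oxidase (ENSMUSG00000022742, chromosome 16, 58670292 to 58717636, mm10), rose from 40.7 ± 0.947 CPM (SD, n = 2) to 301 ± 42.0 CPM (SD, n = 4), a log2 change of 2.89 ± 0.29. Fech, which inserts iron into protoporphyrin to form heme, rose by 2.11 ± 0.28, Alad by 1.76 ± 0.32, Urod by 1.53 ± 0.19 and Ppox by 0.52 ± 0.13. Alas2, the erythroid first enzyme, had a change of 0.88 ± 0.36 (edgeR adjusted p = 0.0832), Alas1 of -0.60 ± 0.28 (0.134) and Uros of 0.43 ± 0.42 (0.471). Among all 15916 tested genes edgeR called 31.8% at day 14, 2686 higher and 2377 lower, and each list's count stands beside this share. Of the 9 heme synthesis genes 6 were called higher and 0 lower, and 7 were higher when adjusted over the list alone (camera adjusted p = 6.67e-04, median 1.53). With an estimated correlation the adjusted p = 0.262. The call of Ppox was lost without day 14 on replicate 1 (edgeR adjusted p = 0.0729), without day 14 on replicate 2 (0.0764) and with no low-count filter (0.0834).

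**Figure D1:**
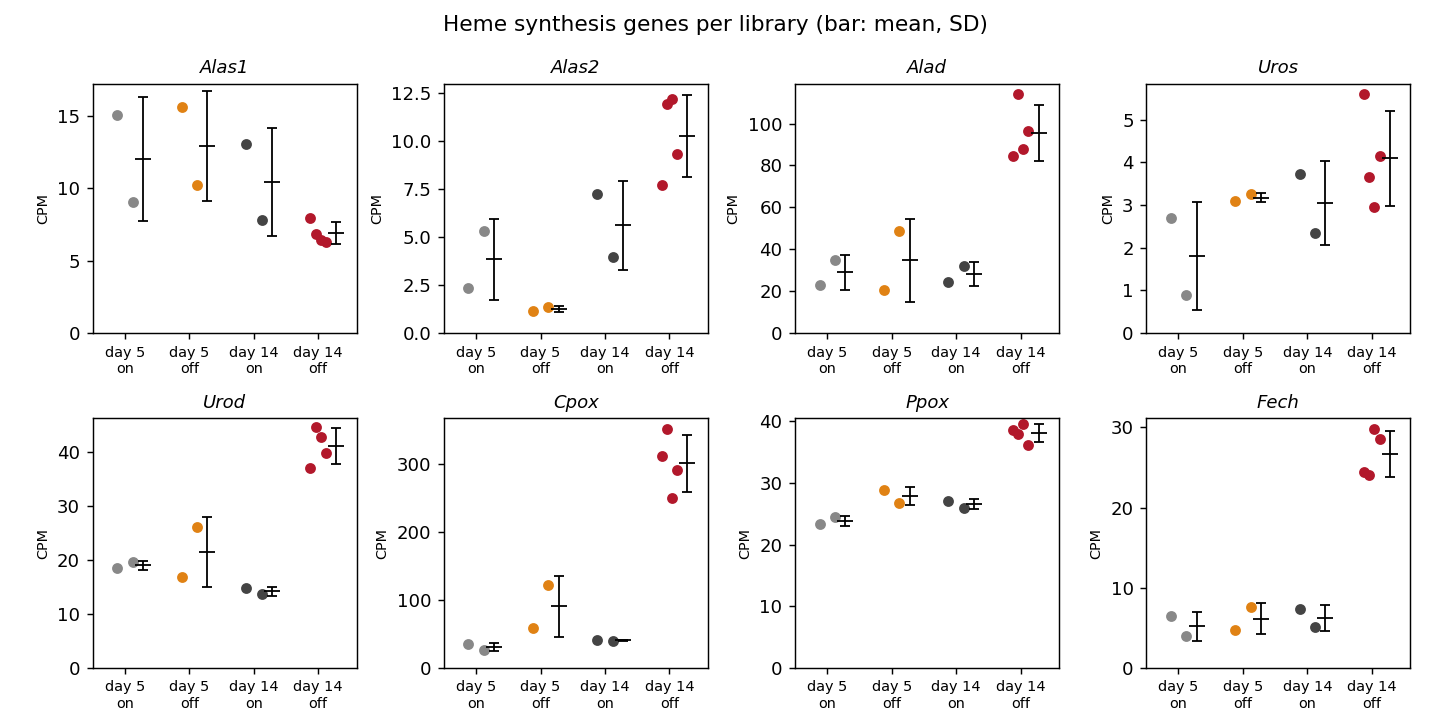
CPM (vertical axis, linear from 0) of 8 heme synthesis genes in each library by group, with points for libraries and bars for the group mean and SD. The 4 day 14 off libraries lie above both day 14 on libraries for Alad, Urod, Cpox, Ppox and Fech.

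Markers of red cell precursors rose with the heme genes at day 14. Car1, an early erythroid carbonic anhydrase (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368), went from 12.0 ± 2.94 CPM (SD, n = 2) to 1201 ± 50.3 CPM (SD, n = 4), a log2 change of 6.65 ± 0.65. Ermap, a red cell membrane protein, rose by 5.26 ± 0.49 and Epor, the erythropoietin receptor, by 4.18 ± 0.44. Of the 24 tested erythroid genes 17 were called higher and 0 lower, and 21 were higher when adjusted over the list alone (median 3.45, camera adjusted p = 3.36e-11). With an estimated correlation the adjusted p = 0.262. In 3 of these genes the list overlaps another list. Heme transport genes had 9 of 17 higher and 1 lower, 10 and 1 adjusted over the list alone, with Abcb6 at 2.52 ± 0.23 and Tmem14c at 1.24 ± 0.14 (camera adjusted p = 0.00203, and adjusted p = 0.262 with an estimated correlation). Iron genes had 7 of 17 higher and 3 lower, 8 and 4 adjusted over the list alone, without a call for the list (camera adjusted p = 0.108). Among them Steap3, a ferrireductase, rose by 3.85 ± 0.28 and Slc11a2, an iron transporter, by 2.87 ± 0.21.

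Of the gene groups named in the series title's question, copper genes had 8 of 19 called higher and 0 lower, or 8 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.00586, and adjusted p = 0.262 with an estimated correlation). Without day 14 off replicate 3 the median was 0.25. Mt2, a metal-binding metallothionein, rose by 5.73 ± 0.49, from 22.0 ± 2.89 CPM (SD, n = 2) to 1167 ± 162 CPM (SD, n = 4). Of 19 genes of protein lipoylation and cuproptosis 5 were higher and 0 lower, or 6 and 1 adjusted over the list alone (median 0.36). Called in either direction, 5 of 19 is a smaller share than the 31.8% over all tested genes. Camera gave an adjusted p = 0.0358, and an adjusted p = 0.321 with an estimated correlation. Dlst and Dlat, lipoylated subunits of mitochondrial enzyme complexes, rose by 0.85 ± 0.12 and 0.69 ± 0.18, and Fdx1, a mitochondrial ferredoxin, had a change of -0.07 ± 0.17 (edgeR adjusted p = 0.80). The list's call was lost without day 14 on replicate 1 (camera adjusted p = 0.0735) and without day 14 off replicate 3 (0.0688), and that of Dlat without day 14 on replicate 1 (edgeR adjusted p = 0.140). Of the copper list's 21 genes 11 stand in another list, as do 7 of the 20 lipoylation genes.

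Mitochondrial gene groups were higher at day 14. The mitochondrial ribosome had 40 of 78 genes called higher and 1 lower (44 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 1.46e-09). Mrpl17 changed by 1.04 ± 0.16 and Mrpl18, which shares its counts with Tcp1, by 0.94 ± 0.13. Complex I had 23 of 36 higher and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 1.20e-07). Ndufb9 changed by 0.94 ± 0.14 and Ndufa9 by 0.79 ± 0.12. Complex IV had 11 of 32 higher (11 and 0 adjusted over the list alone, camera adjusted p = 0.00145). Cox6a1 changed by 0.80 ± 0.14 and Ndufa4 by 0.84 ± 0.16. Mitochondrial chaperones and proteases had 9 of 12 higher (9 and 0 adjusted over the list alone, median 0.93, camera adjusted p = 4.12e-05). Afg3l2 changed by 1.28 ± 0.16 and Htra2, which shares its counts with Loxl3, by 1.62 ± 0.20. With an estimated correlation the adjusted p = 0.262 for these 4 lists. Iron-sulfur assembly had 11 of 26 higher (11 and 0 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.441 with an estimated correlation). Iba57 changed by 2.07 ± 0.29. The tricarboxylic acid cycle had 8 of 18 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.00203, and adjusted p = 0.30 with an estimated correlation). Suclg2 changed by 1.16 ± 0.18. Genes encoded in the mitochondrial genome had 6 of 13 higher (8 and 0 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.441 with an estimated correlation). mt-Cytb changed by 0.81 ± 0.15 and mt-Nd4l by 1.28 ± 0.24. ATF4 stress response genes had 14 of 29 higher and 2 lower (14 and 3 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.409 with an estimated correlation). Gars changed by 1.0 ± 0.13 and Mthfd2 by 1.24 ± 0.17. The ATF4 call was lost without day 14 on replicate 1 (camera adjusted p = 0.0603).

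Cell cycle genes were also higher at day 14. DNA replication genes had 21 of 23 called higher and 0 lower (23 and 0 adjusted over the list alone, median 1.29, camera adjusted p = 3.54e-13). Ccne1, cyclin E1, changed by 2.91 ± 0.21 and Cdc6 by 2.22 ± 0.17. Mitosis genes had 17 of 18 higher (18 and 0 adjusted over the list alone, median 1.48, camera adjusted p = 6.17e-11). Cdk1 changed by 1.74 ± 0.19 and Top2a by 1.32 ± 0.15. Replication histones had 34 of 66 higher and 2 lower (35 and 3 adjusted over the list alone, median 1.09, camera adjusted p = 1.46e-09). Hist1h2aj changed by 2.16 ± 0.16 and Hist1h2ae by 1.84 ± 0.14, each sharing its counts with an overlapping gene. Small RNA genes, which like these histones lack a poly(A) tail, had a median of 0.96 (n = 199 genes). With an estimated correlation the adjusted p = 0.262 for these 3 lists. MYC and ribosome biogenesis genes had 20 of 24 higher (20 and 0 adjusted over the list alone, camera adjusted p = 2.31e-08, and adjusted p = 0.274 with an estimated correlation). Odc1, ornithine decarboxylase, changed by 1.52 ± 0.16 and Nolc1 by 1.23 ± 0.17. NRF2 antioxidant genes had 3 of 11 higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.0125, and adjusted p = 0.262 with an estimated correlation). Nqo1 changed by 4.84 ± 0.71 and Gclm by 2.39 ± 0.25.

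Granulocytic genes were lower at day 14, as were Emp1, Cd34 and Kit. Emp1 (ENSMUSG00000030208, chromosome 6, 135362545 to 135383173) fell from 86.0 ± 25.2 CPM (SD, n = 2) to 0.895 ± 0.434 CPM (SD, n = 4), a log2 change of -6.60 ± 0.38. Cd34, a progenitor surface protein, changed by -4.78 ± 0.60 and Kit, the sort marker, by -1.44 ± 0.12. Kit was at 51.3 and 56.2 CPM at day 5 on and 88.9 and 98.1 at day 14 on. In the off libraries it was at 43.3 and 40.3 at day 5 and 30.9 to 36.4 at day 14. The Kit difference at day 14 thus also reflects higher levels in the day 14 on libraries. Stem cell genes had 9 of 25 called lower and 3 higher, 9 and 4 adjusted over the list alone, with Fli1 at -1.10 ± 0.12 and no call for the list (camera adjusted p = 0.0791). Granulocyte progenitor genes had 5 of 10 lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0150, and adjusted p = 0.409 with an estimated correlation). Gfi1, a transcription factor, changed by -2.32 ± 0.43. Neutrophil genes had 4 of 17 lower and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.0359, and adjusted p = 0.557 with an estimated correlation). Called in either direction, their share lay below the 31.8% over all tested genes. Padi4 changed by -3.68 ± 0.30, Itgam, which encodes the Cd11b of the sort, by -2.28 ± 0.56, and Mmp9 by 1.18 ± 0.28. Without day 14 on replicate 1 the calls of both lists were lost (camera adjusted p = 0.161 and 0.198), as were those of Itgam (edgeR adjusted p = 0.140) and Mmp9 (0.0613). The neutrophil call was also lost without day 14 off replicate 3 (camera adjusted p = 0.101), in protein-coding genes without a count-sharing partner (0.0504) and with fry (0.127), and that of Mmp9 without day 14 on replicate 2 (edgeR adjusted p = 0.0730).

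Further groups were lower at day 14. RAS and MAPK output genes had 7 of 15 called lower and 0 higher (7 and 0 adjusted over the list alone, median -1.06, camera adjusted p = 2.82e-04). Etv4 changed by -3.62 ± 0.50 and Ccnd1, which shares its counts with an overlapping gene, by -1.19 ± 0.19. Cholesterol synthesis genes had 13 of 20 lower (14 and 0 adjusted over the list alone, median -0.76, camera adjusted p = 9.86e-06). Hmgcs1, an early enzyme of the pathway, changed by -1.72 ± 0.18. Antigen presentation genes of class I had 8 of 14 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.00102). H2-Q7 changed by -0.80 ± 0.14 and H2-Q4 by -0.62 ± 0.15. With an estimated correlation the adjusted p = 0.321 for these 3 lists. Without day 14 on replicate 2 the RAS and MAPK median was -0.47 (camera adjusted p = 0.00376). Inflammatory NF-kB genes had 5 of 14 lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.409 with an estimated correlation). Cxcl2 changed by -1.90 ± 0.27 and Ccl4 by -1.99 ± 0.29. Without day 14 on replicate 1 the calls of the NF-kB list (camera adjusted p = 0.0864) and of H2-Q4 (edgeR adjusted p = 0.107) were lost.

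The remaining lists were not called at day 14. Interferon genes had 2 of 36 higher and 3 lower (camera adjusted p = 0.349). Ifi203 changed by -3.32 ± 0.33 and Ddx60 by 2.96 ± 0.39. Immediate early genes had 1 of 15 higher and 3 lower (0.244 by camera), p53 targets 3 of 13 higher and 2 lower (0.984 by camera), and BCL2 family genes 2 of 14 higher and 4 lower (0.244 by camera). Bcl2, an inhibitor of apoptosis, changed by -2.37 ± 0.32 and Bbc3 by -1.24 ± 0.14. Glycolysis genes had 5 of 17 higher and 2 lower (camera adjusted p = 0.650). Hk1 changed by 2.50 ± 0.25. DNA methylation and IDH genes had 3 of 11 higher and 2 lower (camera adjusted p = 0.718). Uhrf1 changed by 1.35 ± 0.24. Cytosolic ribosome genes had 10 of 83 higher (camera adjusted p = 0.113), with Rpl41 at 0.49 ± 0.11 and Rps2 at 0.60 ± 0.13, calls lost without day 14 on replicate 1 (edgeR adjusted p = 0.0679 and 0.0690), and for Rpl41 without day 14 on replicate 2 (0.0505). Among cell type markers, monocyte genes had 7 of 19 lower (camera adjusted p = 0.0735), with Klf4 at -1.78 ± 0.29, and megakaryocyte genes 3 of 13 higher and 3 lower (0.683 by camera), with Gp5 at 3.31 ± 0.38 and Itga2b at -2.84 ± 0.32. T and NK cell genes had 6 of 20 lower and 1 higher (camera adjusted p = 0.183), B cell genes 2 of 10 lower (0.183 by camera), dendritic cell genes 3 of 16 lower (0.113 by camera), with Tcf4 at -1.81 ± 0.19, and mast cell genes 3 of 8 lower and 1 higher (0.470 by camera). Nuclear long noncoding RNAs had 1 of 5 lower (camera adjusted p = 0.349). Too few genes were tested for camera in the eosinophil list (1 of 2 higher), the stroma list (1 of 4 higher and 1 lower) and the sex chromosome list (0 of 4 called by edgeR).

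Over all genes, 5063 of 15916 were called by edgeR at day 14, 2686 higher and 2377 lower, and 2874 of them changed at least 2-fold. Besides Car1 and Mt2, the largest rises were Slc25a21 at 6.53 ± 0.93, Ces2g at 6.32 ± 0.61, Epdr1 at 5.99 ± 0.64, Phlda2 at 5.86 ± 0.57, Chst1 at 5.85 ± 1.0 and Col5a1 at 5.64 ± 0.69. Besides Emp1 and Cd34, the largest falls were Cttn at -5.72 ± 0.50, Serpinb10 at -5.53 ± 1.13, the growth factor genes Fgf3 at -5.47 ± 0.64 and Fgf15 at -4.88 ± 0.63, the growth factor receptor gene Fgfr1 at -5.34 ± 0.43, and Lcn4 at -5.26 ± 0.61. Of the vector genes, Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443) was 34.8 ± 3.40 CPM off (SD, n = 4) and 64.7 ± 12.6 CPM on (SD, n = 2), a log2 change of -0.90 ± 0.16 (edgeR adjusted p = 0.00186). Idh2 had a change of -0.03 ± 0.25 and Nras of -0.22 ± 0.12, with edgeR adjusted p = 0.932 and 0.195. A 3′ tag from a vector transcript need not fall in the mouse gene, so Dnmt3a does not check the labels. Without day 14 on replicate 1 the count was 2985, and without day 14 on replicate 2 it was 3269.

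The day 5 comparison asks which of these changes are present early. The erythroid list was again higher off than on, with most of the rise in 1 library (mean log2 CPM 3.15 and 4.70 in day 5 off replicates 1 and 2, against 2.49 and 2.52 on). Rhag, a red cell membrane protein, rose by 4.14 ± 0.66, from 0.469 ± 0.186 to 8.68 ± 7.46 CPM (SD, n = 2 each), Car1 by 3.66 ± 0.59 and Ces2g, a carboxylesterase, by 4.11 ± 0.63. The other large rises were Phlda2 at 3.70 ± 0.64, Epdr1 at 3.51 ± 0.61, Cbx6 at 3.43 ± 0.45, Mpzl2 at 3.38 ± 0.41 and Gp5 at 3.19 ± 0.57. The largest fall was Chd4, a chromatin remodeller (ENSMUSG00000063870, chromosome 6, 125095981 to 125130591), at -2.52 ± 0.33, followed by Lair1 at -1.88 ± 0.29, mt-Ty at -1.57 ± 0.27, Serpina3g at -1.53 ± 0.26, Gmfg at -1.44 ± 0.25, Selenop at -1.44 ± 0.22, Serpinb1a at -1.27 ± 0.20 and AB124611 at -1.3 ± 0.22. In heme synthesis 0 of 9 genes were called by edgeR and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0840), with Cpox at 1.55 ± 0.30 (edgeR adjusted p = 0.0563) and Alas2 at -1.63 ± 0.48 (0.167). Alad, Urod, Fech, Ppox, Uros and Alas1 had edgeR adjusted p from 0.462 (Uros) to 0.918 (Alas1). Dnmt3a had a change of 0.15 ± 0.19, Idh2 of -0.59 ± 0.29, Nras of 0.12 ± 0.14, Kit of -0.36 ± 0.15, Itgam of 0.87 ± 0.69 and Fdx1 of -0.23 ± 0.20, none called by edgeR.

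In all, 77 genes were called by edgeR at day 5, 59 higher and 18 lower, against 2374 at an unadjusted p of 0.05. This count rests on the fit. It was 0 with limma voom (2323 unadjusted), 0 in a fit of the 4 day 5 libraries (1294 unadjusted), 472 with DESeq2 and 992 without a low-count filter. With 1 library left out it was 0 without day 14 off replicate 1 or 4, 9 without day 14 off replicate 2 or 3, 145 and 2 without day 5 off replicate 1 and 2, and 304 and 9 without day 5 on replicate 1 and 2, by edgeR. All 18 called day 5 genes carried through the alternatives lost their call with limma voom (adjusted p from 0.0513 to 0.195), in the fit of the 4 day 5 libraries (edgeR adjusted p from 0.306 to 0.427) and without day 14 off replicate 1 or 4 (edgeR, highest 0.0913 and 0.0904). Of the 18, 16 lost it without day 14 off replicate 2 (edgeR adjusted p up to 0.0745), 17 without day 14 off replicate 3 (0.0643), 16 without day 5 off replicate 2 (0.240) and 16 without day 5 on replicate 2 (0.191). Without day 5 off replicate 1 and day 5 on replicate 1 it was 3 each (edgeR adjusted p up to 0.110 and 0.062), and 1 each without day 14 on replicate 1 and 2 (0.0513 and 0.0527).

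Of the lists, 11 were called by camera at day 5 and 0 with an estimated correlation (2 at an unadjusted p of 0.05), and fry called 1. Erythroid genes had 3 of 24 higher and 15 and 1 adjusted over the list alone (median 2.22, camera adjusted p = 8.24e-09). Without day 5 off replicate 2 the median was 0.91 (camera adjusted p = 1.58e-04). Neutrophil genes had a median of -1.22 with 0 of 17 called by edgeR, and 7 lower adjusted over the list alone (camera adjusted p = 3.78e-06), with Wfdc21 at -2.10 ± 0.52. Without day 5 on replicate 1 their median was -0.65 (camera adjusted p = 0.0151). Cytosolic ribosome genes had a median of -0.35 with 0 of 83 called by edgeR, and 28 lower adjusted over the list alone (camera adjusted p = 8.78e-21), with Rpl34 at -0.52 ± 0.12. Ribosomal protein genes took 10.8% and 12.1% of the counts at day 5 off and 13% and 15.7% at day 5 on, each with an exact Clopper-Pearson 95% interval within 0.0224 percentage points. For these 3 lists, for NRF2 genes (3 of 11 higher adjusted over the list alone, camera adjusted p = 0.00864, Nqo1 at 3.66 ± 0.78) and for iron genes (camera adjusted p = 0.0227, with Slc11a2 higher at 1.41 ± 0.22), the adjusted p = 0.587 with an estimated correlation. Mitosis (median 0.35, camera adjusted p = 0.00143), DNA replication (median 0.23, 0.00152), class I antigen presentation (median -0.26, 0.0137, with H2-Q6 lower at -0.97 ± 0.15), mast cell (median 0.76, 0.0216) and copper genes (median 0.25, 0.0410) had an adjusted p = 0.725 with an estimated correlation. Replication histones had a median of -0.29 (camera adjusted p = 0.00336, and adjusted p = 0.773 with an estimated correlation). Without day 5 on replicate 1 the calls of copper, iron, NRF2, mitosis, replication, class I and histone lists were lost (camera adjusted p from 0.200 to 0.807), and the histone median was 0.09. Without day 5 off replicate 2 the calls of copper, iron, NRF2, DNA replication and class I lists were lost (camera adjusted p from 0.0776 to 0.228), and 6 of the 11 lists kept theirs. Without day 5 on replicate 2, 7 lists that kept their call had medians moved by over 1.5 times, to -0.21 for the cytosolic ribosome, 0.64 for mitosis, 0.44 for DNA replication, 0.11 for copper, -0.46 for histones, 0.81 for NRF2 (from 0.33) and 0.45 for iron (from 0.16). The iron median was 0.31 without day 5 off replicate 1. The mast cell median was 1.24 without day 5 off replicate 2 and 1.82 without day 5 on replicate 1, and its call was lost without day 5 off replicate 1 (0.157) and without day 5 on replicate 2 (0.359, median -0.06).

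Most genes called at day 14 had changes of the same sign at day 5, as Car1 and Emp1 did. Of the 59 genes called higher at day 5, 55 were called higher at day 14, against 9.96 expected for independent lists, and of 18 called lower 13 were called lower at day 14, against 2.69 expected. No gene was called in opposite directions by edgeR. Of the 2686 genes higher at day 14, 73.5% had a positive change at day 5, and of the 2377 lower genes 77.2% had a negative one. As sets they had medians of 0.22 and -0.31 at day 5 (camera p = 8.07e-18 and 3.50e-16, with an estimated correlation p = 0.0337 and 0.00252, and fry p = 0.0140 and 0.00108). Across genes the changes at both days had r = 0.530, where genes are not independent replicates. The comparisons use different control libraries but share 1 estimate of the spread and the same gene filter, so their calls are not independent. A fit of only the day 5 libraries called 0 genes by edgeR (1294 unadjusted). The expected numbers are therefore a rough guide and not a test of the overlap.

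**Figure D2:**
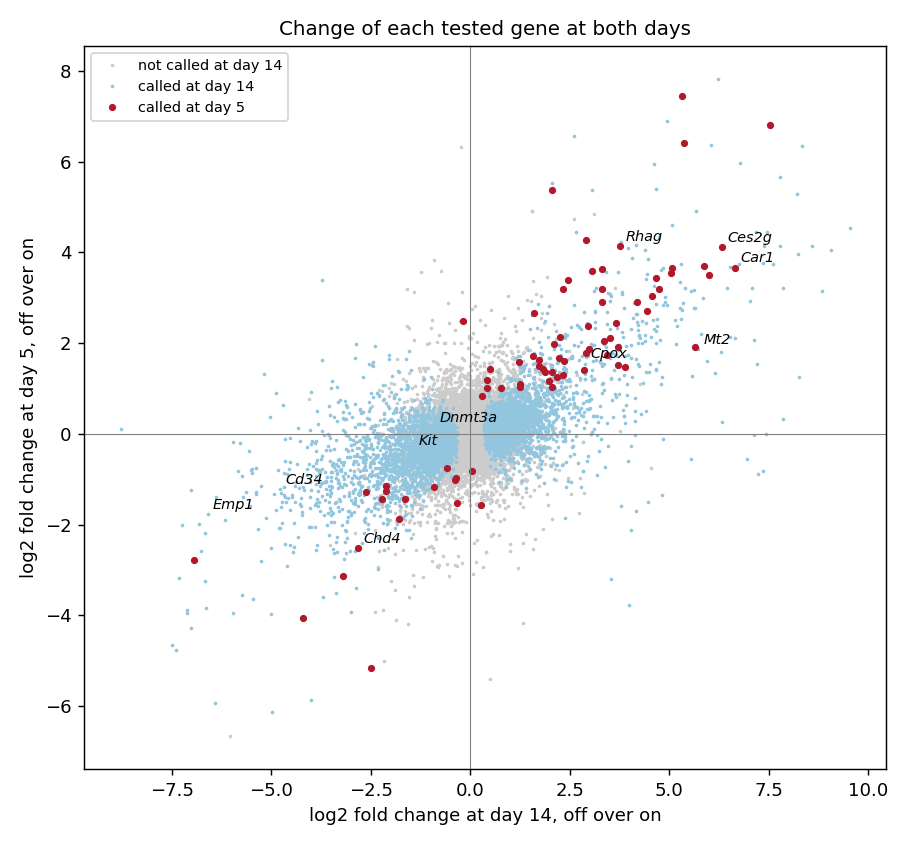
Log2 fold change off over on of each tested gene at day 14 (horizontal axis) and day 5 (vertical axis), 1 point per gene, coloured by edgeR calls. Of the 77 genes called at day 5, 68 were called in the same direction at day 14.

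With both days in 1 model, off against on (6 and 4 libraries), Car1 was again among the largest rises. Ces2g rose by 5.46 ± 0.58, Car1 by 5.27 ± 0.72, Slc25a21 by 5.19 ± 0.74, Phlda2 by 5.06 ± 0.52, Samd14 by 4.85 ± 0.58, Epdr1 by 4.81 ± 0.59, Atp1b2 by 4.77 ± 0.51 and Col5a1 by 4.47 ± 0.66. The largest falls were Emp1 at -4.51 ± 0.81, Fgfr1 at -4.05 ± 0.58, Lcn4 at -4.01 ± 0.55, Thsd1 at -3.65 ± 0.48, Cttn at -3.63 ± 0.72, Ak4 at -3.61 ± 0.63, Myl10 at -3.32 ± 0.51 and Cd34 at -3.32 ± 0.72. Of the heme synthesis genes 6 of 9 were called higher, also 6 adjusted over the list alone, with Cpox at 2.30 ± 0.31, Fech at 1.33 ± 0.36, Alad at 1.10 ± 0.34, Urod at 0.93 ± 0.26 and Ppox at 0.39 ± 0.11 (camera adjusted p = 0.00264, and adjusted p = 0.535 with an estimated correlation). The model fits 1 common effect to both days, while no heme synthesis gene was called at day 5. The effects of Fech and Urod differed between days (edgeR adjusted p = 0.0432 and 0.0339). They were 2.11 and 1.53 at day 14, and 0.28 and 0.18 at day 5. Kit, Emp1, Cttn and Fgfr1 also differed between days. With a block for replicate number the calls of Alad, Fech, Urod, Ppox, Emp1 and Cttn were lost, and whether these numbers pair the libraries is not settled. Alad, Fech, Urod and Ppox lost their call without day 14 on replicate 1 (edgeR adjusted p = 0.180, 0.105, 0.113 and 0.105) and without day 14 on replicate 2 (0.189, 0.127, 0.146 and 0.139). Without 1 of the other libraries the calls of Alad (day 14 off replicates 1 to 4, day 5 off replicate 2, day 5 on replicate 1, edgeR adjusted p from 0.0694 to 0.103), Ppox (day 14 off replicates 1 to 4, 0.0578 to 0.069) and Urod (day 14 off replicates 1 and 4, 0.0508 and 0.0521) were also lost. Kit fell by 1.0 on the log2 scale (SE 0.18), while Dnmt3a had a change of -0.46 ± 0.20 (edgeR adjusted p = 0.118), Idh2 of -0.27 ± 0.21, Nras of -0.07 ± 0.11, Itgam of -1.07 ± 0.63, Alas1 of -0.30 ± 0.23, Alas2 of -0.08 ± 0.48, Uros of 0.60 ± 0.32 and Fdx1 of -0.14 ± 0.13.

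Camera called 21 lists over both days, 16 higher and 5 lower, and 19 of 90 splits of the libraries within their days, the real one included, called at least as many. The erythroid list had 16 of 24 genes higher (17 adjusted over the list alone, median 3.04, camera adjusted p = 1.32e-11). Rhag changed by 3.87 ± 0.38 and Epor by 3.74 ± 0.39. Replication genes had 14 of 23 higher (20 adjusted over the list alone) with Rrm1 at 1.2 ± 0.20, mitosis genes 14 of 18 (17 adjusted over the list alone) with Birc5 at 1.20 ± 0.19, and NRF2 genes 4 of 11 (7 adjusted over the list alone) with Nqo1 at 4.36 ± 0.54. Neutrophil genes had 8 of 17 lower (8 adjusted over the list alone), with S100a9 at -1.16 ± 0.23, and class I genes 7 of 14 lower (7 adjusted over the list alone), with H2-Q7 at -0.76 ± 0.11. With an estimated correlation the adjusted p = 0.535 for these 6 lists. The other lists called by camera as higher were heme transport, copper, complex IV, complex I, the tricarboxylic acid cycle, the mitochondrial genome, the mitochondrial ribosome, ATF4, mitochondrial chaperones, MYC and replication histones (camera adjusted p from 4.22e-07 to 0.0301), and as lower cytosolic ribosome (0.0226), RAS and MAPK (0.0111) and cholesterol synthesis (0.0124). None of these 14 lists was called with an estimated correlation (camera adjusted p from 0.535 to 0.810). Lipoylation and cuproptosis genes, with 4 of 19 higher, were not called (camera adjusted p = 0.0558). The largest camera adjusted p with 1 library left out, among lists that lost their call, was 0.0697 for the tricarboxylic acid cycle and 0.0604 for the mitochondrial genome (both without day 14 on replicate 1). It was 0.168 for ATF4 (without day 14 on replicate 1, and 0.0633 and 0.0896 without day 14 off replicate 1 and day 5 on replicate 1) and 0.0988 for RAS and MAPK (without day 14 on replicate 2, and 0.0533 without day 5 on replicate 2). For cholesterol synthesis it was 0.119 (camera, without day 14 on replicate 2, and 0.0752 and 0.0525 without day 14 on replicate 1 and day 5 on replicate 1), and for the cytosolic ribosome 0.583 (without day 5 on replicate 2, and 0.318 and 0.201 without day 5 off replicate 1 and 2). Over all genes 3153 were called by edgeR, 1571 higher and 1582 lower, against 1348 with a block for replicate number. The count was 1871 without day 14 on replicate 1 and 1129 without day 14 on replicate 2.

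**Figure D3:**
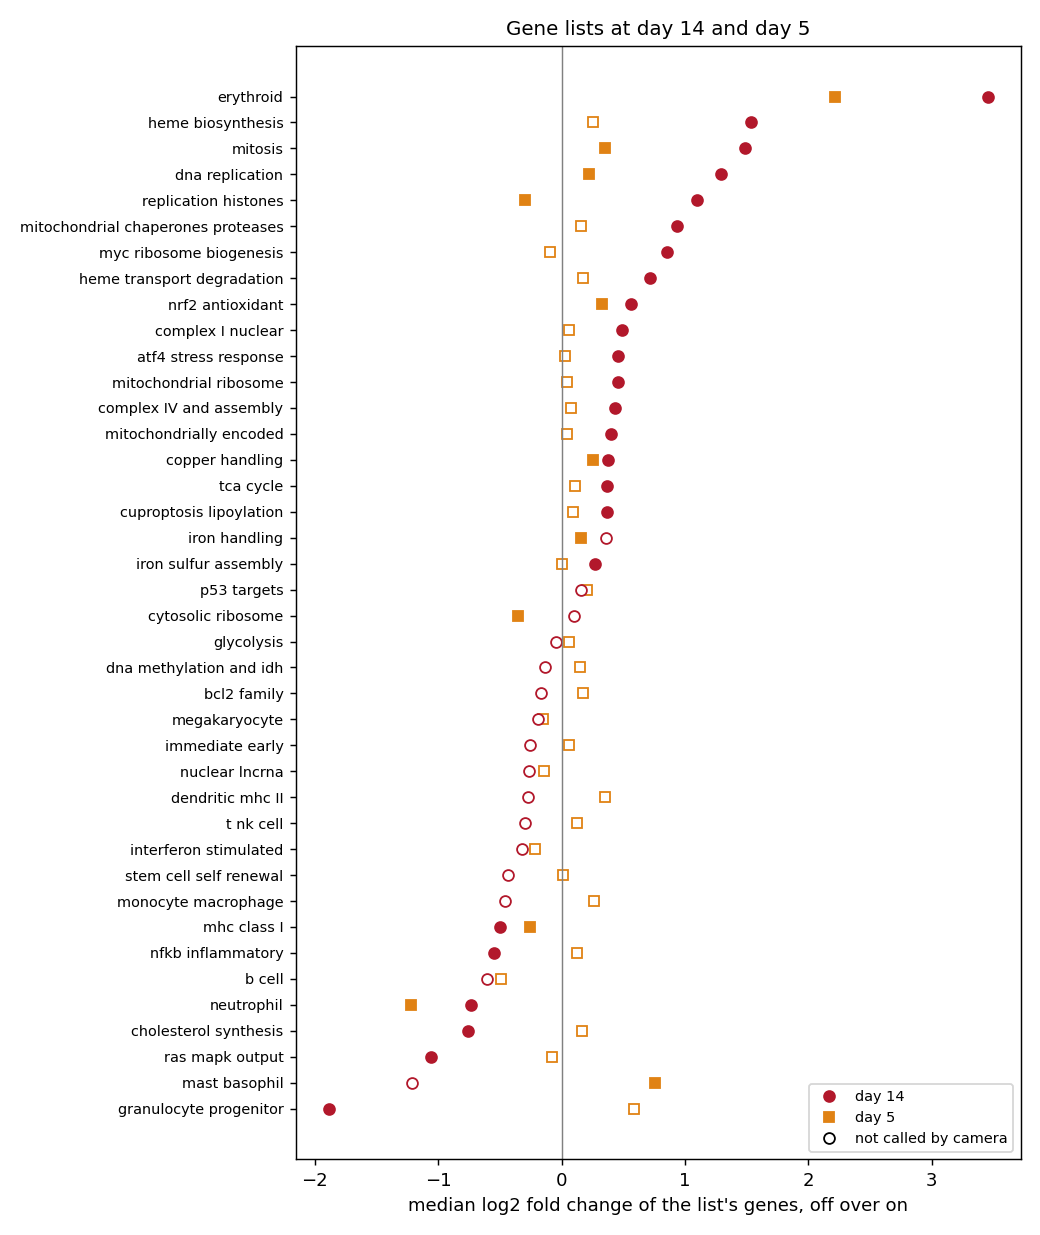
Median log2 fold change off over on (horizontal axis) of the tested genes of each of the 40 lists (vertical axis) at day 14 and day 5, with open symbols for lists that camera with the preset correlation did not call. The erythroid list lies highest at both days, at 3.45 and 2.22.

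The difference between the day 14 and day 5 effects asks which effects depended on the day. Histone genes led the positive differences, Hist1h2aj (annotated as a pseudogene) at 2.85 ± 0.23 and the predicted genes Gm44357 at 2.87 ± 0.24, which shares its counts with Hist1h2aj, and Gm11336 at 2.18 ± 0.20. Their effects had opposite signs, at 2.16, 2.19 and 1.70 at day 14 and -0.69, -0.68 and -0.48 at day 5, and the 199 small RNA genes had medians of 0.96 and -0.17. Among the latter, 57 snRNA genes had medians of 1.35 and 0.18. Tnfrsf13b at -2.30 ± 0.27, Emp1 at -4.83 ± 0.56 and Ahnak at -3.26 ± 0.42 led the negative ones. Of the heme genes, Alas2, Urod and Fech differed between days, at 2.51, 1.35 and 1.83 (edgeR adjusted p = 0.0494, 0.0339 and 0.0432). These differences were not carried through the alternatives. The effect on Alas2 was 0.88 at day 14 and -1.63 at day 5, when it was at 1.13 and 1.38 CPM off and 2.36 and 5.33 CPM on. In all 487 genes differed by edgeR, 262 with a more positive and 225 with a more negative effect at day 14. The count was 1957 without a low-count filter and 1327 with DESeq2. Left out in turn, day 14 off replicates 1, 2 and 4 gave 106, 209 and 111, day 14 on replicates 1 and 2 gave 180 and 130, day 5 off replicate 1 gave 107 and day 5 on replicate 1 gave 965.

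Without doxycycline, the change from day 5 to day 14 was a control for time. Samsn1 rose by 1.13 ± 0.14, Bbc3, a p53 target that promotes apoptosis, by 1.37 ± 0.17 and Foxj2 by 1.61 ± 0.22, while Gm44357 changed by -1.67 ± 0.18, Hist1h2aj by -1.62 ± 0.18 and Gm11336 by -1.22 ± 0.15. EdgeR called 370 genes, 154 higher and 216 lower. All 6 named genes lost their call without day 14 on replicate 1 (edgeR adjusted p from 0.126 to 0.162), where 0 genes were called against 2200 at an unadjusted p of 0.05, and in a fit of the 4 on libraries (edgeR, 0 called, 1633 unadjusted), while DESeq2 called 1136. Gm11336 also lost its call without day 14 on replicate 2 (edgeR adjusted p = 0.0562). Leaving out day 14 off replicates 1 to 4 gave 37, 65, 223 and 38 genes, day 14 on replicate 2 gave 31, day 5 off replicates 1 and 2 gave 191 and 176, and day 5 on replicates 1 and 2 gave 187 and 680. Without a filter 1275 were called.

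On doxycycline, Aplp2 rose from day 5 to day 14 by 1.79 ± 0.16, Ammecr1 by 2.61 ± 0.23 and Uhrf1bp1 by 1.86 ± 0.18. Tnfrsf13b, a receptor of B cell survival factors, changed by -2.02 ± 0.17, Serpinb1a by -1.97 ± 0.17 and Atp8b4 by -2.17 ± 0.19. EdgeR called 2706 genes, 1601 higher and 1105 lower. The count was 1566 and 1717 without day 14 off replicate 1 and 2, and 601 and 1283 without day 5 off replicate 1 and 2.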

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

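The tests of admixed cells, of doxycycline itself and of S phase, the fits without the 3 ribosomal RNA locus genes and with thinned counts, and the list tests on the difference between days were chosen after the results were seen.

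Single libraries lay apart from the other 3 day 14 off libraries in 13 of 181 values tested, where chance alone gives about 9.05. Replicate 2 was high for Slc11a2 at 67.2 CPM (others 62.0 to 62.7), Odc1 at 450.1 (366 to 374), Bcl2 at 48.6 (21.8 to 25.0) and Glrx5, an iron-sulfur assembly gene, at 347 (297 to 301). Replicate 4 was low for Cox6a1 at 147 CPM (169 to 174), mt-Cytb at 1800 (1910 to 1922) and H2-Q6 at 32.4 (38.5 to 39.7), and high for Tal1, an erythroid transcription factor, at 50.3 (29.6 to 31.4). Replicate 3 was low for Rrm1 at 152 CPM (193 to 196) and high for Bcl2a1a at 68.6 (31.3 to 37.7). Mean log2 CPM was high for class I genes in replicate 1 at 6.96, for p53 targets in replicate 2 at 4.15 and for BCL2 family genes in replicate 3 at 5.23.

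The effect of doxycycline differed between day 14 and day 5 in 487 genes by edgeR's test of the difference, 46 of them among the 156 named genes. More positive at day 14 on the log2 scale were Alas2 2.51, Urod 1.35, Fech 1.83, Mt2 3.87, Steap3 2.56, Slc11a2 1.46, Iba57 1.86, Ndufb9 0.89, Ndufa9 0.82, Ddx60 3.45, Cdk1 1.48, Top2a 0.99, Ccne1 2.0, Cdc6 1.56, Odc1 1.23, Nolc1 1.32, Hk1 1.85, Slc16a1 1.43, Hist1h2aj 2.85, Hist1h2ae 2.11, mt-Ty 1.84, Rrm1 1.02, Hist1h2ac 1.98, Rrm2 1.11, Gm44357 2.87, Gm11336 2.18, Uhrf1bp1 1.87. More negative were Dnmt3a -1.05, Kit -1.08, Emp1 -4.83, Cttn -4.32, Fgf3 -4.60, Fgfr1 -3.24, Fgf15 -5.78, Trp53inp1 -1.80, Bcl2 -2.34, Ccnd1 -1.40, Hmgcs1 -1.80, Padi4 -2.61, Itga2b -2.53, Serpinb1a -1.34, Tnfrsf13b -2.30, Ahnak -3.26, Samsn1 -0.78, Foxj2 -1.21, Atp8b4 -1.81.

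Camera with the preset correlation called a difference between days in 26 lists, and 0 with an estimated correlation (4 at an unadjusted p of 0.05), while fry called 17. The median differences on the log2 scale were more positive at day 14 for heme synthesis 1.34, heme transport 0.55, copper 0.29, iron-sulfur assembly 0.39, complex IV 0.35, complex I 0.46, tricarboxylic acid cycle 0.36, mitochondrial genome 0.31, mitochondrial ribosome 0.44, cytosolic ribosome 0.44, ATF4 0.39, mitochondrial chaperone 0.86, mitosis 0.94, DNA replication 1.03, MYC and ribosome biogenesis 0.87, erythroid 1.38, replication histone 1.40. They were more negative for stem cell -0.46, granulocyte progenitor -1.87, NF-kB -0.90, immediate early -0.31, BCL2 family -0.36, RAS and MAPK -1.40, cholesterol synthesis -0.93, mast cell -1.70, dendritic cell -0.55.

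Erythroid and heme genes were higher at day 14 off, and 23 genes of both lists were called. Without the 3 ribosomal RNA locus genes all 23 stayed called, with a median of 3.50 before and after, and with every library thinned to the smallest depth all 23 stayed called with a median of 3.33, which argues against both as the whole cause. Admixed erythroid cells of 1 fixed kind cannot be told apart from a change in the leukaemic cells, since 1 late gene (Epb42) was called: it reached 4.47% of its day 14 rise in day 5 off replicate 1, where early genes reached 1.72% to 8.59%, and 71.4% in replicate 2, where early genes reached a median of 26.8%. Of the globins, abundant in red cells, Hba-a1, Hba-a2 and Hbb-bs were higher in each day 14 off library than in both day 14 on libraries, at 1.51, 1.07 and 0.87 on the log2 scale, and Hbb-bt was at -0.12 (edgeR adjusted p = 0.0511, 0.0974, 0.136 and 0.860). In day 5 on replicate 2 Hbb-bt was at 2416 CPM, above every off library, and Hbb-bs at 658 CPM. Early genes were low there, with Gata1 at 1.35 and Klf1 at 0.83 CPM. A cKit sort is meant to remove mature red cells but not precursors that carry cKit, so it does not bear on admixture of such precursors. Whether RNA of mature red cells passed the sort was not tested. The unlabelled origin in marrow or spleen stays open, as it was not tested.

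Mitochondrial genes were higher at day 14 off. Doxycycline, which can block mitochondrial translation, was given to every off library, and its direct effect cannot be told apart from that of the vector. At day 5 the chaperone list had a camera adjusted p = 0.299 and the ATF4 list 0.638, which leaves it open. With a cycling score in the model 1 of 3 lists stayed called (complex I, camera adjusted p = 8.74e-04, against 0.550 for the mitochondrial ribosome and 0.699 for chaperones). The score was 6.26 to 6.55 at day 14 off and 4.99 to 5.09 on, so that more cycling cells cannot be told apart from the treatment.

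Replication histones were higher at day 14 off and lower at day 5. Histone transcripts lack a poly(A) tail, and 199 small RNA genes that also lack one had medians of 0.96 at day 14 and -0.17 at day 5, so a difference in capture between libraries may contribute. More cells in S phase cannot be told apart from it: at day 5 the histone median was -0.29 and that of replication genes 0.23, but without day 5 on replicate 1 the histone median was 0.09.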

How the results depend on the processing

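The fits without the ribosomal RNA locus genes, of protein-coding genes without a count-sharing partner and with thinned counts were chosen after the data were seen. An arm left with 1 library was assumed to vary like the other groups, and for the changes below the cause was not tested, except that a 2-fold minimum removes genes by construction.

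With a 2-fold minimum edgeR called 2874 genes at day 14, 1585 over both days, 174 from day 5 to day 14 on and 1282 off. Without a low-count filter it called 992 at day 5, 1957 for the difference between days and 1275 over time on. With the replicate block the counts were 225 at day 5, 1348 over both days, 1521 for the difference and 1014 over time on. Under the block 25 calls of named genes over both days were lost, among them Alad, Fech, Urod, Ppox, Emp1 and Cttn, and so were the calls of lipoylation genes at day 14 (camera adjusted p = 0.0767), iron genes at day 5 (0.0544) and cholesterol synthesis over both days (0.105). The labels do not say what the replicate numbers share. Residuals of the 12 pairs of libraries with the same number all correlated positively, at 0.03 to 0.33, with 2 pairs at or below 0.1. Some pairs with different numbers lay within that range. Day 14 off replicate 3 and day 14 on replicate 1 were at 0.185, and day 14 off replicate 4 and day 5 on replicate 1 at 0.176. In groups of 2 libraries the residuals mirror each other, so these pairs are not separate results. Replicate 1 also lay above replicate 2 in each group for the dendritic cell markers given below. Whether the numbers pair the libraries is not settled. DESeq2 called 472, 1327 and 1136 at day 5, for the difference and over time on. At day 5 limma voom called 0 (2323 unadjusted), and edgeR fits of only the compared groups called 0 at day 5 (1294 unadjusted) and 0 over time on (1633 unadjusted). Protein-coding genes without a partner gave 246 over time on. Lists called with an estimated correlation by camera were 0 at day 14, 0 at day 5 and 0 over both days (3, 2 and 1 unadjusted), and fry called 1 at day 5, 25 at day 14 and 15 over both days.

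With 1 library left out, edgeR called 2985 to 5738 genes at day 14, 0 (2035 unadjusted) to 304 at day 5, 1129 to 4120 over both days, 106 to 965 for the difference, 0 (2200 unadjusted) to 680 over time on and 601 to 3409 off. Of the 5063 genes at day 14, 2779 were shared without day 14 on replicate 1 and 3023 without day 14 on replicate 2. Lists called by camera were 19 to 27, 7 to 15 and 18 to 26 at day 14, day 5 and over both days.

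Changes of sign were limited to genes without a call. At day 14 Idh2 was 0.14 with the block, 0.040 with limma voom and -0.48 to 0.55 with 1 library left out, and Fdx1 -0.18 to 0.030. At day 5 such ranges were -0.043 to 0.33 for Dnmt3a, -0.012 to 0.26 for Nras, -0.59 to 1.60 for Itgam, -0.21 to 0.49 for Alas1, -0.49 to 0.74 for Alad, -0.17 to 0.46 for Urod and -0.10 to 0.64 for Fech. Over both days Alas2 was 0.36 with limma voom and -0.61 to 0.41 with 1 library left out. Called list medians that changed sign were those of mast cell genes at day 5 (-0.06 without day 5 on replicate 2) and of replication histones (0.09 without day 5 on replicate 1).

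Of named-gene results with 1 library left out, 2256 kept direction and side of the threshold, 210 lost their call and 17 gained one. Under the alternatives set before these were 1528, 77 and 41, and under the added ones 728, 3 and 2. For lists 525 were kept and 35 lost with 1 library left out, 202 and 78 under other alternatives set before and 164 and 4 under added ones. Medians of day 14 genes at day 5 differed by 0.53, by 0.459 with separate fits of each day and by 0.457 with the block. Genes near the zero-count limit of 0.209 to 0.323 CPM are limited by depth.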

Other observations

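The genes named in this part and the test of the Chd4 region were chosen after the values were seen, while the splits were set before.

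Chd4 was 1137 and 2629 CPM at day 5 on and 2959 and 4353 at day 14 on, against 309 to 349 at day 5 off and 477 to 550 at day 14 off, a log2 change of -2.69 ± 0.21 over both days (edgeR adjusted p = 3.00e-04). A hypothesis was that the whole region around Chd4 may have changed. Among tested genes within 100 kb, 13 do not overlap Chd4, and their changes ran from -0.47 to 1.90 with a median of 0.051, with Pianp (1.90) and Mrpl51 (0.66) called higher (edgeR adjusted p = 0.00668 and 0.0103). This argues against a fall of the whole region by as much as Chd4. Gm23751, which lies inside Chd4, was at -3.17. Akap5, an anchoring protein of kinase A, fell by 1.02 on the log2 scale over both days (SE 0.20, edgeR adjusted p = 0.00714). Its change was -1.29 ± 0.24 at day 14 (edgeR adjusted p = 0.00262) and -0.65 ± 0.29 at day 5, where it was not called (0.328).

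Markers of cross-presenting dendritic cells were present in every library. Xcr1 was 86.1 to 494 CPM, Clec9a 42.0 to 155, Batf3 18.5 to 84.1, Irf8 388 to 1632, H2-Aa 820 to 2226 and Cd74 144 to 587. In each of the 4 groups replicate 1 had a higher level of each of these 6 genes than replicate 2. EdgeR called 0 of these 6 genes in the day 14, day 5 and both-days comparisons, with Xcr1 over both days at 0.82 ± 0.38 (edgeR adjusted p = 0.148).

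Of 90 splits of the libraries within their days, 1, the real one, called as many as 3153 genes with edgeR, and the highest other called 1573. Chance is therefore an unlikely source of the count over both days, but it is not excluded. The splits were run without the replicate block, with which the real count was 1348, and were not repeated with the block. For lists, 19 of the 90 splits called at least the 21 of the real one and the highest other called 29, so chance cannot be excluded.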
